A study of Mus musculus with 24 samples.

How the data were processed

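Poly(A) RNA from the skin of 24 mice was sequenced, 4 mice in each of 6 groups formed by 3 treatments and 2 days. Control mice received saline by injection and solvent on the skin, model mice received dihydrotestosterone (DHT, an androgen) by injection and solvent on the skin, and treatment mice received DHT and a topical extract of the Hanlianxiang (HLX) formula, a traditional Chinese medicine preparation. Groups were taken from the sample titles, and each library is 1 mouse.

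The authors extracted RNA with TRIzol, prepared libraries with a VAHTS Universal V6 kit, trimmed reads with fastp, aligned them with HISAT2 to the mouse genome build GRCm39 and counted reads per gene with HTSeq. Tool versions, parameters and the annotation release are not stated in the labels. The deposited table gives FPKM (fragments per kilobase of gene, scaled to the fragments of the library) for 18892 gene symbols in 24 columns, and all 24 columns were used. Its column totals run from 413117 to 455945, and no further scaling was applied before the main tests. Coordinates are not printed, because the table gives none.

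Depth was recovered from the table itself. Within a gene, FPKM values of libraries differ by ratios of whole numbers after 1 factor per library, and whole reads were recovered for 18703 of the 18715 genes above 0 in any library (99.9%). The tolerance was 0.01 of a read for low genes and 0.05 for high genes, and the highest deviation was 4.8e-05. Recovered totals run from 3.31e+07 to 3.81e+07 reads per library, and the depth factors of the libraries lie between 0.957 and 1.062 times their mean. Reads carry no molecular identifiers, so the precision of each comparison was taken from the spread between mice and not from counts.

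Values were transformed as log2(FPKM + 1), and genes with an FPKM of at least 1 in at least 4 libraries were tested. This left 13039 genes and removed 5853. One mean per group was fitted to all 24 libraries with limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with trend and robust), with a shared estimate of the spread. Tests were two-sided, p-values were adjusted over genes by the Benjamini-Hochberg method within each of 11 comparisons, and a gene is called when its adjusted p is under 0.05. Differences are given as log2 differences on the log2(FPKM + 1) scale, with the standard error (SE) of the fit, and group levels as mean FPKM with the standard deviation (SD, n = 4). A pseudocount of 1 shrinks differences of genes at low FPKM, and no fold is given against a group listed at 0 in every library.

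The comparisons were model against control and treatment against model at each day (the 4 main comparisons), treatment against control at each day, day 15 against day 10 within each treatment, and 2 tests of whether the model-control or treatment-model difference changed between days. Gene lists, 36 in all, were fixed from textbook knowledge of skin, hair follicle, immune and other cell types and were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over lists within a comparison, and again with the correlation estimated from the data. The test compares a list with all other tested genes. Counts adjusted over the list alone are given beside counts adjusted over all genes.

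Named genes follow a fixed rule. In each main comparison they are up to 10 called genes with the largest rise and up to 10 with the largest fall, with a mean of at least 2 FPKM in the higher group and no overlap between the libraries of both groups, leaving out symbols of unnamed gene models. In each list past the threshold the 4 members with the smallest p were added, and a panel of androgen and follicle genes. Some genes that meet the rule are not reported here, and counts include them. The other comparisons name up to 5 genes per direction, or the 5 smallest p-values where none was called. The comparisons, tests, lists, naming rule and first set of alternatives were chosen before the data were examined. The genes drawn in the plots and the enrichment of Gene Ontology terms were chosen after the values were seen.

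The relation between both effects of a day was measured as a correlation across genes, for which genes are not independent replicates. Because both differences share the model libraries, 100 simulations with residuals dealt to unchanged groups, and 6 splits of the 4 model libraries into 2 and 2, were set beside it. A position along the model-control axis was computed for each library, with 0 the control mean and 1 the model mean of the same day.

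Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, a common total per library, quantile normalization, a fit of only the groups compared, array weights, the replicate number as a block, and leaving out each library in turn. Voom on the recovered reads, a fit without the treatment libraries with low Y-linked transcripts, a fit without the genes of the kidney set and list tests on the changes between days were added after seeing the data. Every comparison was also repeated over other splits of its libraries.

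The rates below hold only for simulated data, as other splits of the real libraries called up to 2891 genes. Of 12978 genes 200 were changed between model and control at day 10. Of these, 36 of 67 genes changed 1.5-fold were called, 54 of 67 at 2-fold and 61 of 66 at 4-fold. Unchanged genes made up 4 calls (2.6%), and 1 gene was called over all comparisons when no change was simulated. Scripts ran under python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.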

Results

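The data are gene expression values of mouse skin in 24 libraries, each from 1 mouse. There were 4 control, 4 model (DHT-injected) and 4 treatment mice (DHT and topical HLX extract) at day 10 and at day 15 each. Per library, 16457 to 16943 genes were above 0. Correlations between libraries of a group, computed across genes (which are not independent replicates), were at least 0.9794 in the 3 groups of day 10 and in the control group of day 15. The lowest values were 0.9428 in the model and 0.9283 in the treatment group of day 15.

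Model against control at day 10 asks what DHT injection changed in skin. S100a7l2, an S100 family gene, went from 2.22 ± 2.21 FPKM (SD, n = 4) in control to 259 ± 116 in model skin, and Defb8, a beta-defensin, from 14.2 ± 3.93 to 861 ± 459. Of 14 macrophage genes 11 rose, Adgre1 among them (14 adjusted over the list alone, adjusted p = 0.536 with an estimated correlation). Of 55 keratin-associated protein genes 33 fell, and 11 of 15 hair shaft keratins (43 and 14 adjusted over the list alone, adjusted p = 0.536 with an estimated correlation for both). Serpinb6e, a serine protease inhibitor family gene, fell from 13.1 ± 1.41 to 0.87 ± 0.551 FPKM, and Hamp2, a hepcidin gene, from 5.46 ± 2.03 to 0.0884 ± 0.177. In all, 1803 of 13039 genes were called. Of these 885 were higher and 918 lower in model skin, 170 and 94 of them by over 2-fold.

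**Figure D1:**
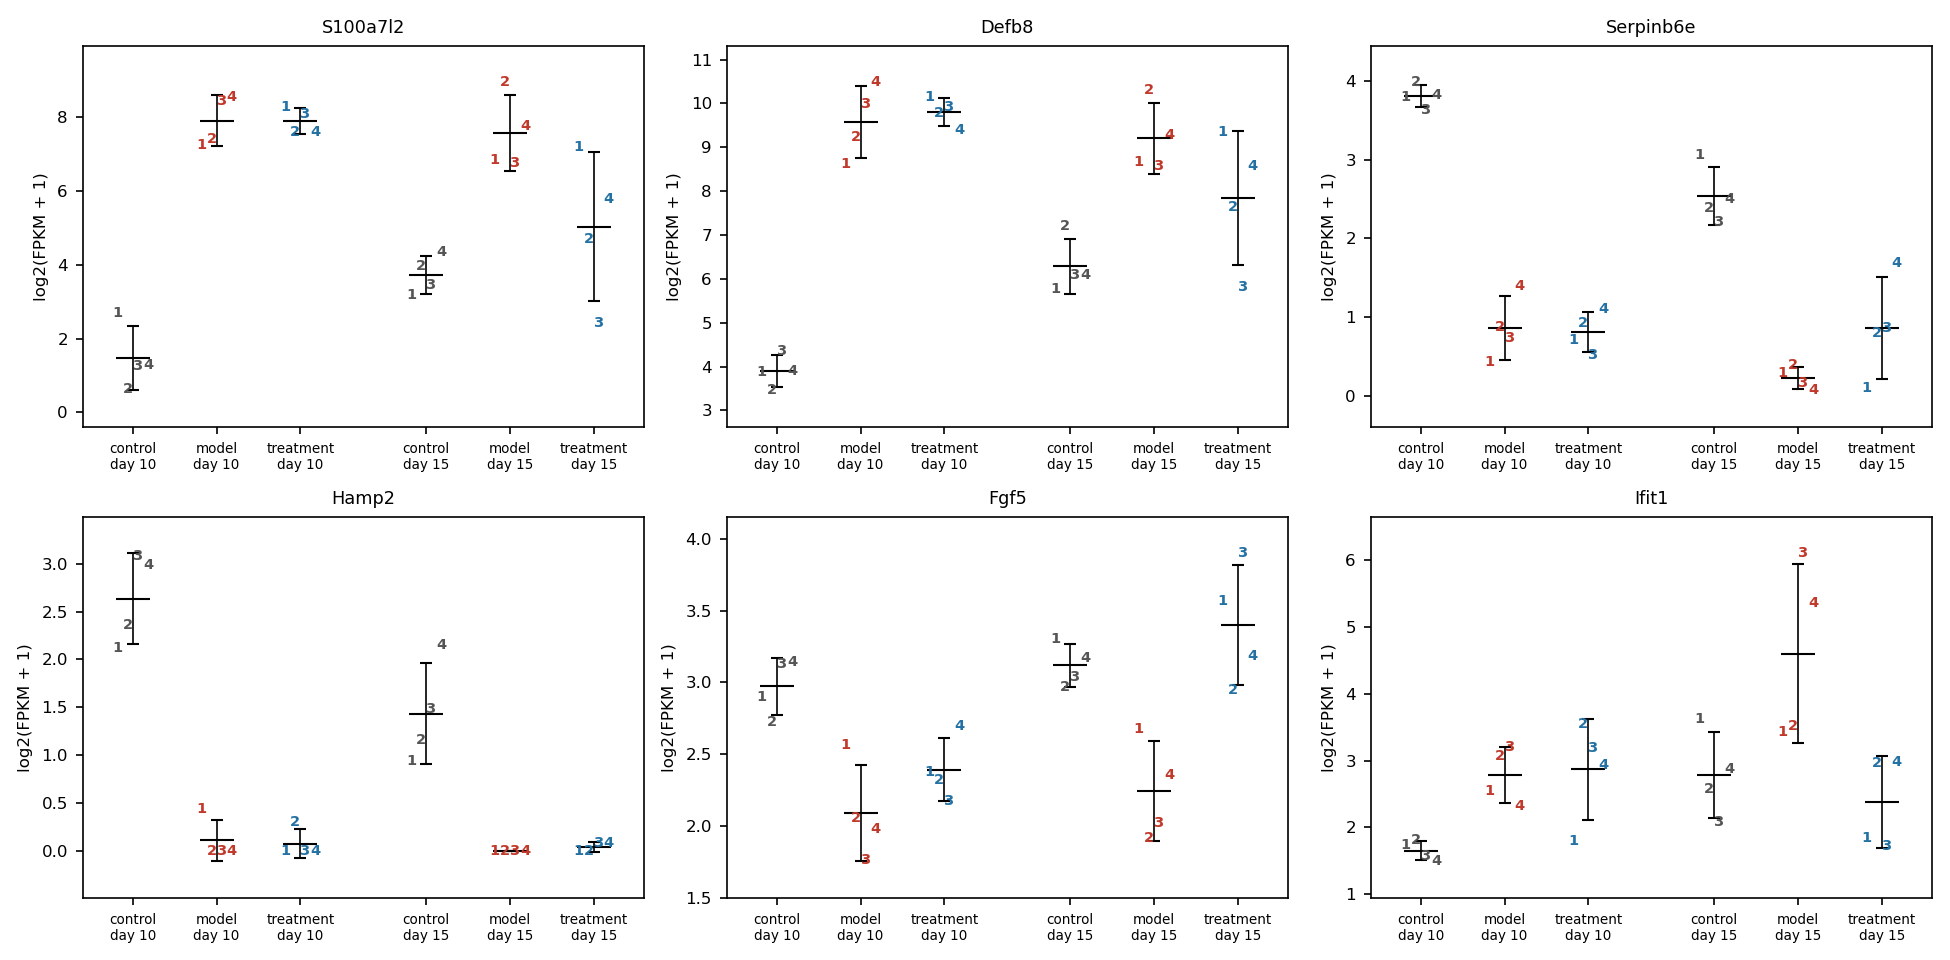
Levels of S100a7l2, Defb8, Serpinb6e, Hamp2, Fgf5 and Ifit1 as log2(FPKM + 1) in the 6 groups; each point is 1 mouse, shown as its replicate number, bars are means and error bars SD (n = 4). Mean S100a7l2 was 2.22 FPKM in control and 259 FPKM in model skin at day 10.

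Among the other largest rises, Saa3, Saa1 and Saa2, serum amyloid A genes of the acute-phase response, had log2 differences of 5.34, 2.42 (SE 0.59) and 2.36 (SE 0.68). S100a9, a calcium-binding protein abundant in neutrophils, differed by 3.17 (SE 0.95, adjusted p = 0.032), and Prg4, which encodes the lubricant lubricin, by 2.79 (SE 0.68). Sult1e1, the estrogen sulfotransferase, rose by 2.74 (SE 0.50) and Ctla2a, a cysteine protease inhibitor gene, by 2.68 (SE 0.50). C7, a component of the terminal complement complex, rose by 2.18 (SE 0.36). Falls of similar kind were those of Cyp2g1, a cytochrome P450 (log2 difference -1.91, SE 0.26), Car6, a secreted carbonic anhydrase (-1.86, SE 0.32), Serpina3b (-1.84, SE 0.27) and Ahsp, a chaperone of alpha-hemoglobin (-1.75, SE 0.24). Krtap20-2 (-1.69), Krtap19-1 (-1.65), Sprr2h, a cornified envelope gene (-1.61), and Atp12a (-1.61) completed the 10 largest falls. The naming rule required libraries of both groups not to overlap for these 20 genes. S100a9 and Saa2 were not called without any 1 of control replicates 1, 3 and 4 or model replicates 2, 3 and 4 (adjusted p up to 0.11 and 0.089). Neither Prg4 nor Saa1 was called without model replicate 2 (adjusted p = 0.056 and 0.052). Voom did not call Saa3, S100a9, Prg4, Saa1 or Saa2.

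Of 55 keratin-associated protein genes, which encode the matrix of the hair fiber, 33 fell and 22 were not called, and 43 fell when adjusted over the list alone (median log2 difference -0.91, adjusted p = 1.29e-19, and adjusted p = 0.536 with an estimated correlation). An example is Krtap15, which went from 2210 ± 499 to 844 ± 536 FPKM. Hair shaft keratins fell in 11 of 15 genes (14 adjusted over the list alone, median -1.12, adjusted p = 2.59e-10, and adjusted p = 0.536 with an estimated correlation), with Krt81 at -1.47 (SE 0.27). Inner root sheath genes fell in 9 of 10 (10 adjusted over the list alone, median -0.74, adjusted p = 4.55e-07, and adjusted p = 0.536 with an estimated correlation), among them Krt72 (-1.13) and trichohyalin, Tchh (-0.97). Hair matrix regulators fell in 6 of 13 (8 adjusted over the list alone, adjusted p = 0.000535, and adjusted p = 0.625 with an estimated correlation), with the transcription factors Prdm1 (-0.65) and Foxn1 (-0.87). Wnt targets fell in 3 of 10 (3 adjusted over the list alone, adjusted p = 0.00939, and adjusted p = 0.625 with an estimated correlation), namely Tcf7, Lef1 and Nkd1. Cholesterol synthesis fell in 1 of 16 (1 adjusted over the list alone, adjusted p = 0.0476, and adjusted p = 0.625 with an estimated correlation). Lef1 (up to 0.12) and Nkd1 (up to 0.17) were not called without any 1 of control replicates 1 and 3 or model replicates 2, 3 and 4, nor Lef1 without control replicate 4. Tcf7 was not called without control replicate 3 or model replicate 3 (adjusted p up to 0.056), nor the matrix regulators Ovol1 and Foxq1 without either of these or model replicate 4 (adjusted p up to 0.085). Nkd1 was not called when only both groups set the spread, with no filter or with a common total per library. The cholesterol list did not pass without any 1 of control replicates 3 and 4 or model replicates 1 and 2 (adjusted p up to 0.138).

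Of 14 macrophage genes 11 rose and 3 were not called (14 adjusted over the list alone, median 1.29, adjusted p = 3.96e-10, and adjusted p = 0.536 with an estimated correlation), among them Mrc1, the mannose receptor (85.8 ± 9.62 against 36.7 ± 4.85 FPKM), and Adgre1, which encodes F4/80 (38.6 ± 6.53 against 13.6 ± 3.32). Dermal extracellular matrix genes rose in 5 of 17 (13 adjusted over the list alone, median 0.78, adjusted p = 6.69e-07, and adjusted p = 0.611 with an estimated correlation), with decorin, Dcn, at 0.83 (SE 0.17) and fibronectin, Fn1, at 0.99 (SE 0.24). Interferon response genes rose in 3 of 13 (7 adjusted over the list alone, median 1.08, adjusted p = 3.96e-05, and adjusted p = 0.625 with an estimated correlation), Oas2 by 1.20 (SE 0.24), Oasl2 and Oas1a. Of 7 neutrophil genes 2 were called, Il1r2 (0.77) and Csf3r (1.72), with 2 adjusted over the list alone (adjusted p = 0.0125, and adjusted p = 0.625 with an estimated correlation). No gene was called by limma or voom in 4 further lists past the threshold: skeletal muscle (21 genes, 4 at an unadjusted p under 0.05, median 0.59), mast cells (7 genes, 2 such, 0.56), antigen-presenting cells (7 genes, 4 such, 0.69) and inflammatory cytokines (13 genes, 4 such, 1.33, with Il1b at 2.61, SE 1.17). Each of these 4 lists had an adjusted p = 0.625 with an estimated correlation. Mammary epithelium genes fell in 3 of 6 (4 adjusted over the list alone, adjusted p = 0.0142, and adjusted p = 0.536 with an estimated correlation), namely Krt18 (-1.29, SE 0.24), Elf5 and Csn3. Neither the neutrophil genes nor Oasl2, Oas1a, Elf5 and Csn3 were called without any 1 of control replicates 1, 3 and 4 or model replicates 2, 3 and 4 (adjusted p up to 0.16). Voom did not call Oasl2, Oas1a or Csn3, and Oas1a and Csn3 were lost with no filter. Csn3 was also lost with a common total per library and when only both groups set the spread, and Oas1a without control replicate 2. Lox and Col5a2, also called matrix genes, were not called without control replicate 3 or model replicate 3, nor Col5a2 without control replicate 4 or model replicates 2 or 4 (adjusted p up to 0.077). Csf3r was also not called without control replicate 2, by voom, with no filter or with median-of-ratios scaling. Without control replicate 4 the mast cell (adjusted p = 0.064) and antigen-presenting lists did not pass, the latter also not without control replicate 3 or model replicates 1, 2 or 4 (adjusted p up to 0.0925). The cytokine list did not pass without model replicate 3 (adjusted p = 0.0656).

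In the androgen and follicle panel, Fkbp5, a classic androgen and glucocorticoid target, rose from 20.9 ± 8.29 to 42 ± 5.24 FPKM at day 10 and Tgfb2 from 4 ± 0.414 to 6.3 ± 0.571. Fgf5, the growth factor that ends hair growth, fell from 6.92 ± 1.06 to 3.36 ± 1.08 FPKM. Bmp2 fell by a log2 difference of -0.69 (SE 0.17), a call that ended without control replicate 3 or model replicate 3 (adjusted p up to 0.058). The 5-alpha reductase Srd5a1 (log2 difference -0.18, SE 0.10), Tgfb1 (0.59, SE 0.20, adjusted p = 0.057), Vegfa (0.33), Igf1 (0.21), Wnt10b (-0.07), Shh (0.13) and Ctnnb1 (-0.19) were not called. Dkk1 and Srd5a2 were under the filter, at 0.06 and 0.1 FPKM in control skin of day 10.

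The count at day 10 was lower without any 1 of 6 libraries: 1017 without control replicate 1, 612 without control replicate 3, 877 without control replicate 4, 681 without model replicate 2, 536 without model replicate 3 and 815 without model replicate 4. With a common total per library the balance turned to 1071 higher and 604 lower genes, and array weights gave 4927 genes.

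Model against control at day 15 asks the same question later. S100a7l2 and Defb8 were again among the largest rises, from 12.9 ± 4.95 to 231 ± 179 FPKM and from 83.3 ± 42.2 to 668 ± 415, and Ctla2a rose from 56.6 ± 13.5 to 495 ± 167. Lysyl oxidase, Lox, rose from 38.5 ± 7.29 to 127 ± 9.1 FPKM, and Krt5, a basal keratin, and Idi2, a gene of isoprenoid synthesis, fell. Of 55 keratin-associated protein genes 28 fell, and 4 of 17 dermal matrix genes rose (42 and 11 adjusted over the list alone, adjusted p = 0.513 with an estimated correlation for both). In all, 1408 genes were called, 552 higher and 856 lower in model skin, 79 and 62 of them by over 2-fold.

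Serpina3k, a serine protease inhibitor gene, rose by 3.05 (SE 0.53), Wfdc12, a WAP-domain gene, by 1.98 (SE 0.40) and C7 by 1.89 (SE 0.36). Saa2 (2.39, SE 0.68), Saa1 (2.38, SE 0.59) and the chemokine gene Ccl12 (2.20, SE 0.54) were called. None of the 3 was called without any 1 of control replicates 2 and 3 or model replicate 3, nor Saa2 and Ccl12 without control replicate 4 (adjusted p up to 0.12). Voom called neither Saa2 nor Saa1. The largest falls were those of Idi2 (-2.34, SE 0.42), Serpinb6e (-2.31, SE 0.25), Serpinb6d (-2.29, SE 0.51), Serpina3b (-2.28, SE 0.27), Sprr2h (-1.88, SE 0.23), the cornified envelope gene Lce3c (-1.58, SE 0.31), Krtap4-13 (-1.53, SE 0.29) and Krtap4-9 (-1.51, SE 0.28). Neuronatin, Nnat (-2.26, SE 0.63), was not called without any 1 of control replicates 2, 3 and 4 or model replicate 3 (adjusted p up to 0.1). Mup20, a major urinary protein gene (-1.96, SE 0.55), was not called by voom, nor without any 1 of control replicates 1, 2 and 3 or model replicates 2 and 3 (adjusted p up to 0.087).

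Of 55 keratin-associated protein genes 28 fell at day 15 (42 adjusted over the list alone, median -0.96, adjusted p = 2.48e-16, and adjusted p = 0.513 with an estimated correlation), with Krtap3-2 from 368 ± 66.7 to 155 ± 48.3 FPKM. Inner root sheath genes fell in 8 of 10 (10 adjusted over the list alone, adjusted p = 4.85e-06, and adjusted p = 0.513 with an estimated correlation). Hair shaft keratins fell in 3 of 15 (10 adjusted over the list alone, adjusted p = 4.02e-05, and adjusted p = 0.513 with an estimated correlation). Hair matrix regulators fell in 4 of 13 (11 adjusted over the list alone, adjusted p = 0.513 with an estimated correlation), of which Dlx3 and Msx2 were among 3 not called when only both groups set the spread. Wnt targets fell in 2 of 10 (2 adjusted over the list alone, adjusted p = 0.513 with an estimated correlation), Tcf7 among them, and neither of the 2 was called in that fit. Cholesterol synthesis genes fell in 5 of 16 (7 adjusted over the list alone, adjusted p = 0.513 with an estimated correlation), and Fdps was among 3 not called in that fit. Basal epidermis genes fell in 2 of 10 (4 adjusted over the list alone, adjusted p = 0.513 with an estimated correlation), Krt5 from 733 ± 38.6 to 461 ± 106 FPKM and Krt14 by a log2 difference of -0.68. Epidermal differentiation genes fell in 5 of 19 (8 adjusted over the list alone, adjusted p = 0.538 with an estimated correlation), Asprv1 from 268 ± 13.8 to 171 ± 19.7 FPKM. Sebaceous gland genes fell in 1 of 12 (2 adjusted over the list alone, adjusted p = 0.538 with an estimated correlation), Acsbg1. Krt14 was not called without model replicate 3 (adjusted p = 0.052), nor Acsbg1 without control replicate 3 or model replicate 3 (adjusted p up to 0.055). Without control replicate 4 or model replicate 2, among other libraries, none of the 3 hair shaft keratins, 4 hair matrix regulators and 2 Wnt targets was called, nor Krt28, Padi3 and Krt26 of the inner root sheath, Fdps and Nsdhl of cholesterol synthesis, or Tgm1, Ivl and Tgm3 of epidermal differentiation (adjusted p up to 0.14). Without model replicate 3 the epidermal differentiation (adjusted p = 0.226) and sebaceous lists (adjusted p = 0.0591) did not pass.

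Dermal extracellular matrix genes rose in 4 of 17 at day 15 (11 adjusted over the list alone, median 0.67, adjusted p = 3.4e-07, and adjusted p = 0.513 with an estimated correlation). Macrophage genes rose in 2 of 14 (7 adjusted over the list alone, adjusted p = 5.18e-06, and adjusted p = 0.513 with an estimated correlation), Cd163 (1.16, SE 0.25) and Mrc1 (0.85, SE 0.19, not called without control replicate 3 at an adjusted p = 0.052). Interferon response genes rose in 4 of 13 (10 adjusted over the list alone, adjusted p = 3.4e-07, and adjusted p = 0.513 with an estimated correlation), Oas2 by 1.17 (SE 0.24). The other 3, Ifi44, Ifit1 and Ifit3, were not called when only both groups set the spread. Endothelial genes rose in 1 of 12, Vwf, which encodes von Willebrand factor (0.65, SE 0.16; 9 adjusted over the list alone, adjusted p = 2.38e-05, and adjusted p = 0.513 with an estimated correlation; not called without model replicate 2 at an adjusted p = 0.053). Neutrophil genes rose in 2 of 7 (6 adjusted over the list alone, adjusted p = 0.000227, and adjusted p = 0.513 with an estimated correlation), Il1r2 among them, and neither was called when only both groups set the spread. Mammary epithelium genes fell in 2 of 6 (3 adjusted over the list alone, adjusted p = 0.513 with an estimated correlation). Without control replicate 2 or 3, among other libraries, the matrix genes Dcn and Col3a1, both neutrophil genes, Ifit1, Ifit3 and the mammary gene Elf5 were not called, nor Ifi44 without control replicate 3 (adjusted p up to 0.16). Further lists passed with no gene called by limma: mast cells (5 of 7 at an unadjusted p under 0.05, median 0.52), inflammatory cytokines (0 of 13, median 1.16), skeletal muscle (2 of 21, median 0.27), Hedgehog pathway (3 of 8, median -0.26, 3 lower adjusted over the list alone), melanocytes (3 of 11, median -0.28) and cell cycle (3 of 27, median -0.13). Voom called 1 skeletal muscle gene and 0 genes of the other 5 lists. These 6 lists had an adjusted p between 0.513 and 0.699 with an estimated correlation. Erythrocyte genes passed with a median of 0.66 while the 1 called member, Slc4a1, was lower (-0.70), and adjusted over the list alone 4 were higher and 1 lower (adjusted p = 0.538 with an estimated correlation). Without model replicate 3 the erythrocyte, mammary, cytokine, muscle, Hedgehog, melanocyte and cell cycle lists did not pass. All of these but cytokines also failed without model replicate 2. The erythrocyte, Hedgehog, mammary and muscle lists failed without control replicate 1. Those of erythrocytes, Hedgehog, cytokines, melanocytes and cell cycle failed without control replicate 3, and erythrocytes without control replicate 2 or model replicate 1 (adjusted p up to 0.824).

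Within the panel at day 15, Fgf5 fell from 7.73 ± 0.91 to 3.84 ± 1.2 FPKM. Bmp2 (-0.66, SE 0.17), Srd5a1 (-0.38, SE 0.10) and Fkbp5 (0.77, SE 0.24) were called. None of them was called without any 1 of control replicates 2, 3 and 4 or model replicates 2 and 3, nor Fkbp5 without model replicate 4 (adjusted p up to 0.065, 0.091 and 0.15). Values that did not pass were those of Tgfb1 (0.47, SE 0.20), Tgfb2 (0.36, SE 0.12, adjusted p = 0.056), Fgf7 (0.77, SE 0.26, adjusted p = 0.057) and Shh (-0.39, SE 0.13, adjusted p = 0.052).

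Leaving out 1 library moved the day 15 count to 500 (control replicate 2), 369 (control replicate 3), 363 (control replicate 4), 2240 (model replicate 1), 501 (model replicate 2) or 500 (model replicate 3). It was 724 when only both groups set the spread, where 19 of the 65 named called genes were lost, Srd5a1, Fkbp5, Acsbg1, Saa2 and the genes named above for that fit among them. With no filter 8 were lost, Fkbp5, Fdps and Ifit3 among them. Fdps was also lost with a common total per library, quantile normalization or voom, and Saa2 with a pseudocount of 0.1. A common total per library turned the balance to 735 higher and 472 lower genes, and array weights gave 4592 genes. No gene passed in limma's test of whether the model-control difference changed between days (352 at an unadjusted p under 0.05, 0 by voom with 333 at an unadjusted p under 0.05). The same test gave 1 gene without control replicate 1 of day 10 or without control replicate 2 or model replicate 1 of day 15, 3 without model replicate 2 of day 15, and 66 with array weights.

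**Figure D2:**
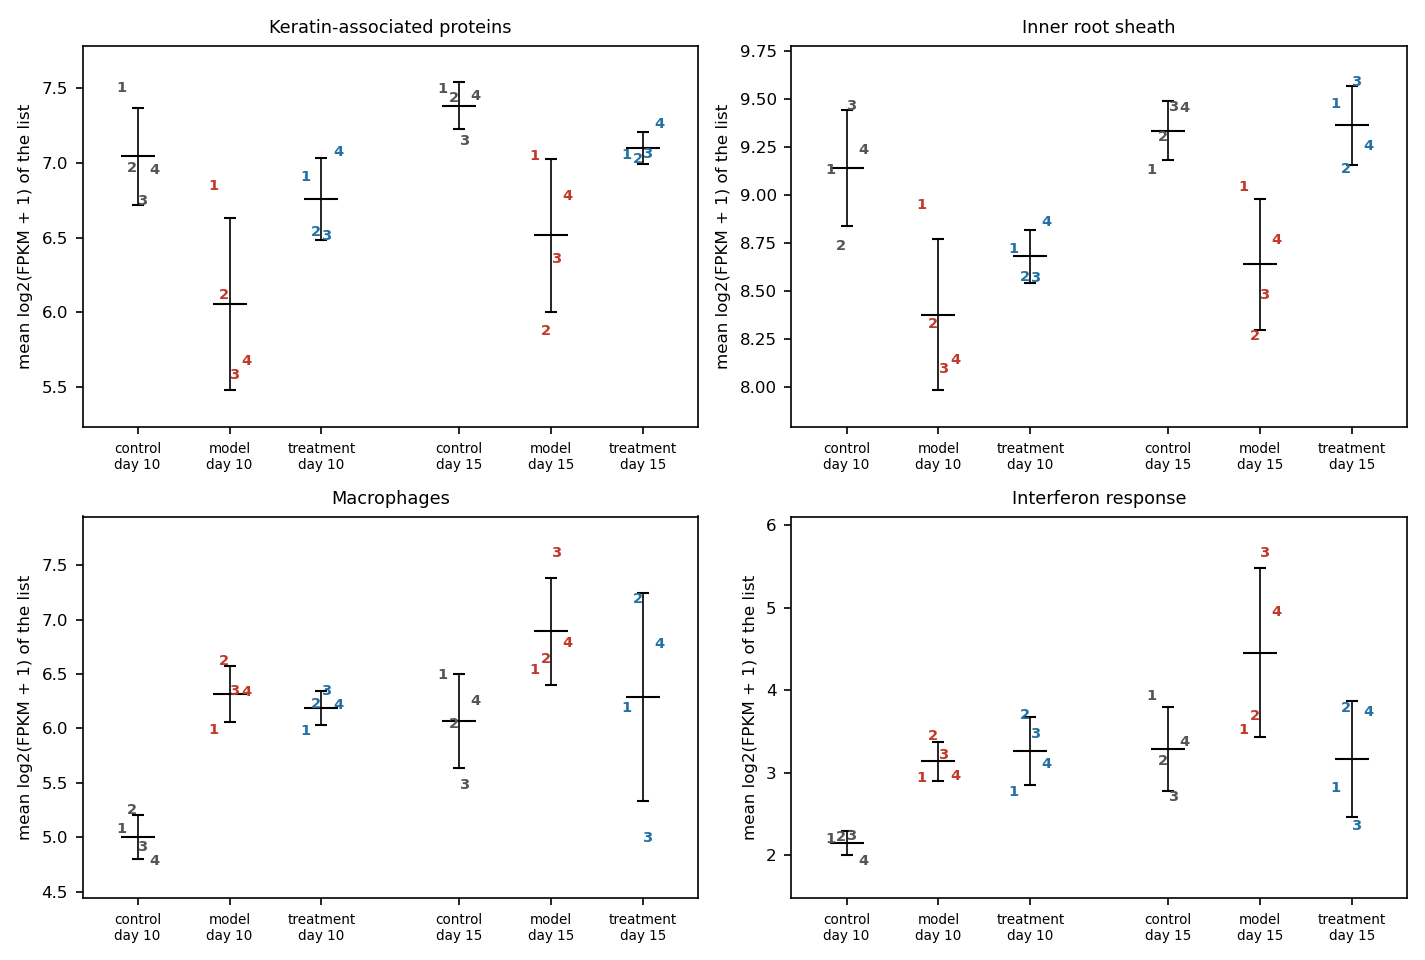
Mean log2(FPKM + 1) over the measured members of 4 gene lists (keratin-associated proteins, inner root sheath, macrophages, interferon response) in the 6 groups; points are mice, shown as replicate numbers, bars are means and error bars SD (n = 4). Median log2 differences of keratin-associated proteins were -0.91 at day 10 and -0.96 at day 15 between model and control skin.

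Treatment against model at day 10 asks what the HLX extract changed in DHT-injected skin, but is confounded by kidney transcripts (below). Krt6a went from 52.1 ± 5.75 to 126 ± 33.5 FPKM (SD, n = 4), Sprr1b from 7.95 ± 2.28 to 33.4 ± 14.2 and Krt16 from 8.81 ± 0.767 to 63.3 ± 36. Of 10 keratinocyte stress genes 6 rose and 4 were not called (7 adjusted over the list alone, median 1.24, adjusted p = 3.27e-14). This list also passed at an adjusted p = 0.0092 with an estimated correlation, in every fit that left out 1 library (adjusted p up to 0.0441 with an estimated correlation). In all 25 genes were called, 12 higher and 13 lower in treated skin, 8 and 7 by over 2-fold, and 1360 had an unadjusted p under 0.05. Voom called 15.

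Other rises were those of Krt6b (2.77, SE 0.50), Sprr2h (1.27, SE 0.23), Nptx1, a pentraxin gene (1.23, SE 0.20), the water and glycerol channel Aqp3 (0.78, SE 0.16, adjusted p = 0.049), Urah (0.65, SE 0.12) and the small heat shock protein gene Cryab (0.62, SE 0.12). Gstt1, a glutathione transferase, fell from 15.9 ± 0.513 to 8.22 ± 1.32 FPKM, Adam33 from 2.14 ± 0.21 to 0.828 ± 0.0506, Hpgds, a prostaglandin D synthase, from 6.98 ± 0.738 to 3.77 ± 0.73 and Poglut3 from 14.3 ± 1.19 to 10.3 ± 0.832. Kap and S100g, genes of kidney tubules, were listed at 0 in every treatment library and at 16.4 ± 2.81 and 2.05 ± 0.131 FPKM in model skin. Kap was at 21.7 ± 1.64 FPKM in control skin of day 10 and at 0 in all libraries of day 15. Without the 7 tested genes of the kidney set, which was defined after seeing the data, 14 genes were called, 9 higher and 5 lower.

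**Figure D3:**
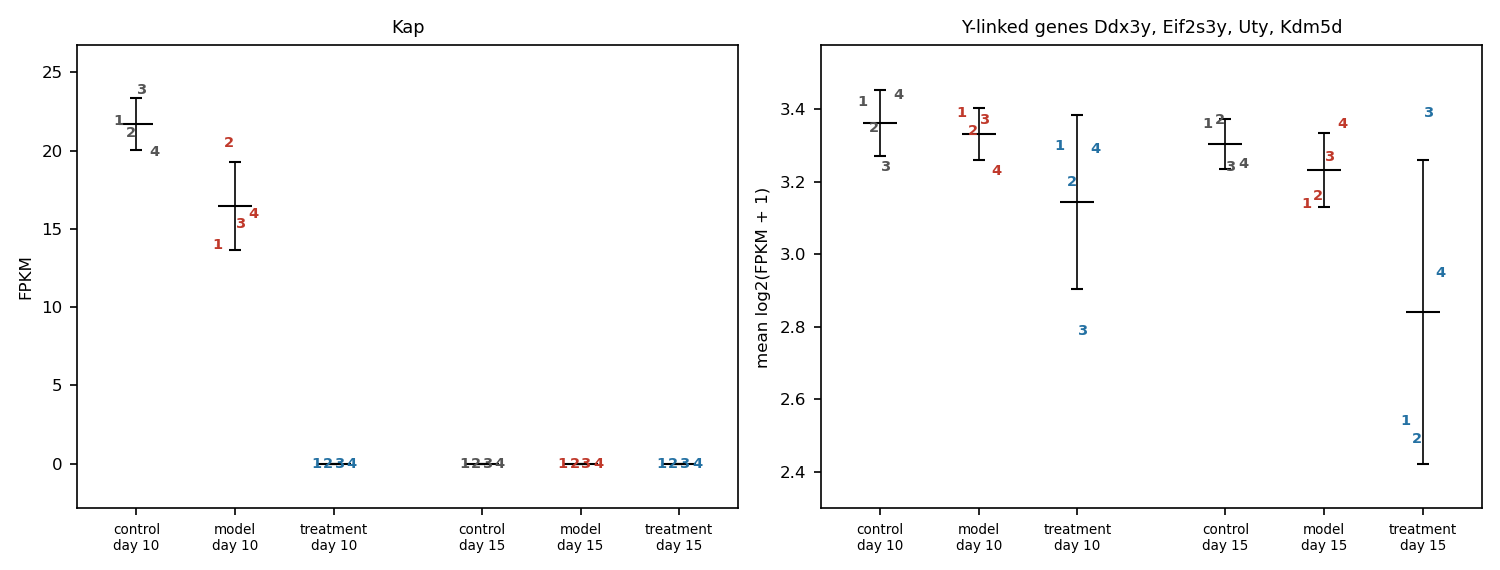
Kap in FPKM and the mean log2(FPKM + 1) of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d in the 24 libraries by group; points are mice, shown as replicate numbers. Kap lies between 14 and 23.8 FPKM in the 8 control and model libraries of day 10 and at 0 in the other 16, and 4 treatment libraries have Y-linked means of at most 2.95 against at least 3.14 in the other 20.

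Xenobiotic and antioxidant response genes passed as a list with no member called by limma or voom (13 genes, 3 at an unadjusted p under 0.05, median 0.19, 2 higher adjusted over the list alone, adjusted p = 0.00134, and adjusted p = 0.0186 with an estimated correlation). The smallest p-values were those of Srxn1 (0.63, SE 0.14, adjusted p = 0.077) and Hmox1, heme oxygenase (1.34, SE 0.35). No keratin-associated protein gene of 55 was called by limma or voom, 37 had an unadjusted p under 0.05, and 32 were higher adjusted over the list alone (median 0.66, adjusted p = 1.28e-31, and adjusted p = 0.266 with an estimated correlation). Hair shaft keratins (0 of 15 called by limma or voom, 9 at an unadjusted p under 0.05, 6 higher adjusted over the list alone, median 0.56) had an adjusted p = 0.313 with an estimated correlation. Basal epidermis genes (0 of 10 called by both, 7 at an unadjusted p under 0.05, 4 higher adjusted over the list alone, median 0.33) had an adjusted p = 0.266 with an estimated correlation. Another 6 lists passed with no gene called by limma (0 to 5 members at an unadjusted p under 0.05, 0 by voom): inner root sheath (median 0.34), erythrocytes (0.43), cell cycle (-0.13), adipocytes (-0.38, Lpl at -0.77), Schwann cells (-0.18) and circadian clock (-0.26, 3 lower adjusted over the list alone, Per3 at -0.68), with adjusted p between 0.523 and 0.968 with an estimated correlation. Single libraries ended the calls of cell cycle (model replicates 1 and 4, treatment replicates 2 and 4), adipocytes (model replicates 1 and 3, treatment replicate 4), Schwann cells (model replicates 2 and 3, treatment replicates 2 and 4) and circadian clock (model replicate 3, treatment replicate 1), with adjusted p up to 0.302. No gene of the panel was called by limma (2 of 18 at an unadjusted p under 0.05, 0 by voom). Shh was at -0.39 (SE 0.13), Vegfa at -0.54 (SE 0.21) and Fgf5 at 0.30 (SE 0.20).

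The day 10 treatment count was 82 without model replicate 1, 15 without model replicate 2, 58 without treatment replicate 1, and 14 without treatment replicate 2, 3 or 4 each. It was 1502 with array weights, 101 with no filter and 10 at a mean FPKM of at least 5. Krt16 was not called without any 1 of treatment replicates 2, 3 and 4 (adjusted p up to 0.063), nor Sprr2h, Urah and Krt6b without any 1 of these or of model replicates 2 and 3 (adjusted p up to 0.11). Aqp3 (up to 0.25) and Cryab (up to 0.21) were not called without any 1 of these or of model replicates 2 and 4, Aqp3 also not without model replicate 3. Hpgds was not called without treatment replicate 2 or 3 (up to 0.063). When only both groups set the spread 30 genes were called, and 9 of the 17 named called genes were not among them, Krt16, Sprr1b, Krt6a, Krt6b, Nptx1, Aqp3, Urah, Cryab and Poglut3. Voom did not call Krt16, Krt6b, Sprr2h, Nptx1, Aqp3 or Cryab. Aqp3 and Cryab were lost with a common total per library or quantile normalization, Aqp3 and Krt6b with a pseudocount of 0.1, and Aqp3 at a mean FPKM of at least 5 and without the kidney set. Treatment replicate 3 had low Y-linked transcripts (mean 2.79 against at least 3.14 in 20 libraries). Without it and the 3 such libraries of day 15 limma called 19 genes, not counting Krt16, Krt6b, Sprr2h, Nptx1, Aqp3 and Cryab.

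Treatment against model at day 15 asks the same 5 days later. Of 55 keratin-associated protein genes 22 rose, and 8 of 13 interferon response genes fell (25 and 10 adjusted over the list alone, adjusted p = 0.726 with an estimated correlation for both). Krtap3-2 went from 155 ± 48.3 to 321 ± 29.2 FPKM (SD, n = 4), Krt85 from 321 ± 66.5 to 589 ± 114, and Ifit1, an interferon-induced antiviral gene, from 32 ± 27.7 to 4.64 ± 2.55. Fgf5 rose from 3.84 ± 1.2 to 9.9 ± 3.17 FPKM and Grem1, a BMP antagonist, fell from 12.5 ± 4.11 to 2.59 ± 1.47. In all 2563 genes were called, 1348 higher and 1215 lower, of which 9 and 91 changed by over 2-fold, and voom called 2574. When only both groups set the spread limma called 0 genes (2503 at an unadjusted p under 0.05). No named gene was called there.

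Of the 4 treatment libraries of day 15, replicates 1, 2 and 4, and at day 10 replicate 3, stood apart with low Y-linked transcripts (means 2.54, 2.49, 2.95 and 2.79 against 3.14 to 3.44 in the other 20 libraries). Without these 4 libraries, a fit chosen after seeing the data, day 15 keeps replicate 3 alone, which is assumed to vary like the other groups and lay at -0.74 on an axis from the control (0) to the model mean (1). The 3845 genes called there (2161 higher, 1684 lower) are thus differences of that 1 library, whose label is left open, from model skin. Of the 72 named called genes 22 lost their call, among them the keratin-associated protein genes named here, Egr1, Smo, Sprr2h and Igf1. Leaving out model replicate 2 gave 1684 genes and leaving out treatment replicate 1 gave 1221. With a common total per library 686 genes were higher and 1676 lower. With array weights Msx2, Pmel, Plk1, Cdc20, Smo, Ptch1, Srd5a1 and Fkbp5 were among 20 named genes not called. Ptch1 and Srd5a1 were among 7 lost with no filter, as was Fkbp5, and among 7 lost with a common total per library, as was Smo.

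Keratin-associated protein genes rose in 22 of 55 at day 15 (25 adjusted over the list alone, median 0.64, adjusted p = 8.64e-09, and adjusted p = 0.726 with an estimated correlation), with Krtap4-7 (1.05), Krtap9-1 (1.02), Krtap2-4, Krtap7-1 (0.97) and Krtap4-1 (0.97) among the largest rises. Without model replicate 2 these 5 were not called (adjusted p up to 0.088), nor Krtap7-1 and Krtap4-1 without treatment replicate 1, nor Krtap4-1 without treatment replicate 4. Hair shaft keratins rose in 10 of 15 (13 adjusted over the list alone, median 0.80, adjusted p = 2.51e-06, and adjusted p = 0.726 with an estimated correlation), Krt85 by 0.88 (SE 0.18) and Krt35 by 0.78 (SE 0.17). Inner root sheath genes rose in 9 of 10 (10 adjusted over the list alone, median 0.73, adjusted p = 2.51e-06, and adjusted p = 0.726 with an estimated correlation), Krt71 from 2130 ± 564 to 3630 ± 161 FPKM. Hair matrix regulators rose in 7 of 13 (12 adjusted over the list alone, adjusted p = 0.726 with an estimated correlation), with Dlx3 at 0.68 (SE 0.16) and Msx2 at 0.74 (SE 0.19). Melanocyte genes rose in 4 of 11 (6 adjusted over the list alone, adjusted p = 0.726 with an estimated correlation), with the pigment genes Tyrp1 (0.74, SE 0.17) and Pmel (0.87, SE 0.22). Cell cycle genes rose in 7 of 27 (9 adjusted over the list alone, adjusted p = 0.726 with an estimated correlation), Plk1 from 6.99 ± 1.67 to 10.8 ± 0.901 FPKM and Cdc20 from 14.3 ± 3.12 to 20.7 ± 1.61. Cholesterol synthesis genes rose in 5 of 16 (7 adjusted over the list alone, adjusted p = 0.726 with an estimated correlation), Fdps by 0.48 (SE 0.08). Mitochondrial oxidative phosphorylation genes rose in 10 of 20 (12 higher and 1 lower adjusted over the list alone, adjusted p = 0.726 with an estimated correlation), Ndufv1 by 0.34 (SE 0.07). Wnt targets rose in 4 of 10 (7 adjusted over the list alone) and Hedgehog pathway genes in 2 of 8, Smo and Ptch1 (3 adjusted over the list alone, adjusted p = 0.726 with an estimated correlation for both). Immediate early genes rose in 4 of 12 (7 adjusted over the list alone, adjusted p = 0.726 with an estimated correlation), Egr1 by 1.51 (SE 0.34), at 75.2, 138 and 121 FPKM in the low-Y replicates 1, 2 and 4 but 31 in replicate 3 (17.6 to 39.9 in model skin). Without treatment replicate 3 the Wnt list (adjusted p = 0.0563) and the Hedgehog list (up to 0.183, also without model replicate 2 or 3) did not pass, nor the immediate early list without treatment replicate 2 (adjusted p = 0.0958). Without model replicate 2 the Wnt targets Tcf7, Rnf43, Nkd2 and Nkd1, the regulators Foxn1 and Ovol1, the melanocyte genes Oca2 and Dct, Krt31, Tpx2 and Junb were not called (adjusted p up to 0.17), and the 4 Wnt targets not with array weights. Neither Smo nor Ptch1 was called without any 1 of model replicates 2 and 3 or treatment replicates 3 and 4, nor Smo without treatment replicate 1 (adjusted p up to 0.15).

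Interferon response genes fell in 8 of 13 (10 adjusted over the list alone, median -1.19, adjusted p = 9.56e-06, and adjusted p = 0.726 with an estimated correlation), with Oas2 from 6.95 ± 3.31 to 1.89 ± 0.837 FPKM, Ifi44 by a log2 difference of -1.29 (SE 0.29) and Ifit3 by -1.70 (SE 0.43). Further large falls were those of Ifit2 (-1.85, SE 0.41), Ifit3b (-1.45, SE 0.31), the interferon-inducible Samd9l (-1.66, SE 0.29), Mndal (-1.59, SE 0.28) and Gbp7 (-1.49, SE 0.29), the inflammatory caspase Casp4 (-1.49, SE 0.34), Ctla2a (-1.85, SE 0.50) and the matrix gene Aspn (-1.59, SE 0.25). Dermal extracellular matrix genes fell in 3 of 17 (1 adjusted over the list alone, median -0.56, adjusted p = 0.00141, and adjusted p = 0.726 with an estimated correlation), Dcn from 1360 ± 260 to 842 ± 215 FPKM. Macrophage genes fell in 2 of 14 (2 adjusted over the list alone, median -0.62, adjusted p = 0.00583, and adjusted p = 0.726 with an estimated correlation), Mrc1 (-0.83, SE 0.19) and Cd163 (-0.95, SE 0.25). Without treatment replicate 3 the matrix list (adjusted p = 0.359) and the macrophage list (adjusted p = 0.548) did not pass, the macrophage list also not without model replicate 3. Cd163 was not called without model replicate 2 (adjusted p = 0.055), nor the matrix genes Lox and Lum without any 1 of model replicates 1, 2 and 4 or treatment replicates 1 and 3 (adjusted p up to 0.16).

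Rises outside the lists were those of Stra6, a retinol transporter (0.99, SE 0.25), Gprc5d, a receptor gene expressed in the hair cortex (0.98, SE 0.23), and Sprr2h (11.1 ± 3.79 to 22.7 ± 4.39 FPKM). In the panel Tgfb2 fell from 5.71 ± 1.31 to 3.62 ± 0.544 FPKM and Igf1 from 16 ± 7.38 to 8.95 ± 0.751. Fkbp5 (-0.74, SE 0.24) was not called without any 1 of model replicates 2 and 4 or treatment replicate 3, nor Srd5a1 (0.31, SE 0.10) without any 1 of model replicates 2 and 3 or treatment replicates 1, 3 and 4 (adjusted p up to 0.13 for each). Tgfb1 (0.03, SE 0.20), Lef1 (0.41, SE 0.17), Shh (0.34, SE 0.13), Vegfa (-0.50, SE 0.21), Wnt10b (0.13, SE 0.21) and Ctnnb1 (0.09, SE 0.09) were not called. Without the low-Y libraries, where replicate 3 alone stands for treated skin, Tgfb1 was at -0.70. The lists of T cells, bulge stem cells, Wnt inhibitors, the BMP pathway, dermal papilla and the panel itself passed in none of the 4 main comparisons (lowest adjusted p = 0.0645).

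Whether the extract moved genes opposite to DHT was measured across genes, which are not independent replicates. At day 15, the treatment-model difference was opposite to the model-control difference in 1385 of the 1408 genes called between model and control (98.4%), with r = -0.749 and rho = -0.714 across genes. Among genes called in both comparisons 505 were lower in model and higher in treated skin, Krtap3-2 and Fgf5 included, 309 were higher and then lower, Oas2 and Ctla2a included, and 0 went the same way. At day 10, 1615 of 1803 genes (89.6%) had opposite differences (r = -0.366, rho = -0.437), and of the genes called in both 3 were lower then higher, 5 higher then lower and 4 went the same way.

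Both differences share the model libraries. Simulated groups with no effect gave a mean r of -0.513 (-0.853 to 0.021) at day 10, further from 0 than measured, and -0.482 (-0.925 to 0.469) at day 15. Their covariance was -0.0275 to 2e-04 at day 10 and -0.0897 to 0.0212 at day 15 against measured values of -0.0291 and -0.0803. Opposite calls in 100 simulations reached at most 0 at day 10, and at day 15 they averaged 14.5 and reached at most 944. With separate pairs of the model libraries r averaged -0.209 at day 10 and -0.447 at day 15, opposite differences 79.6% and 89.4%, and opposite calls ranged from 0 to 2 and from 2 to 160 over 6 splits. Without treatment replicate 3, r at day 15 was -0.49, against -0.838 without treatment replicate 2.

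**Figure D4:**
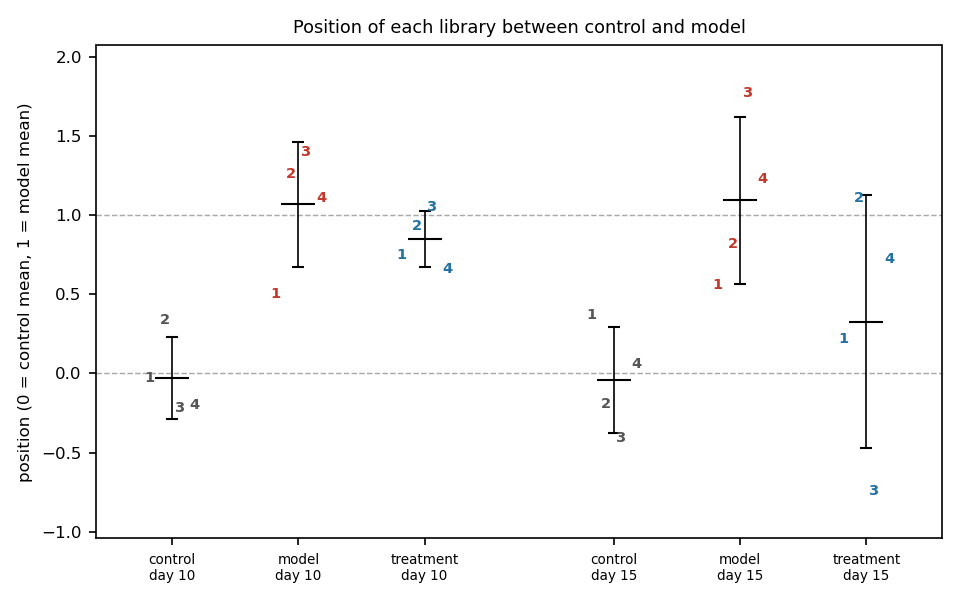
Position of each library on the axis between control (0) and model (1) means of its day; points are mice, shown as replicate numbers, bars are means and error bars SD (n = 4). Treatment libraries average 0.85 (SD 0.17) at day 10 and 0.33 (SD 0.8) at day 15.

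On the axis from the control mean (0) to the model mean (1), treatment libraries of day 10 lay at 0.75, 0.93, 1.05 and 0.66. At day 15 replicates 1 to 4 lay at 0.22, 1.11, -0.74 and 0.72 (control libraries of that day -0.41 to 0.37).

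Treated against control skin at day 10 asks how far treated skin was from untreated skin. S100a7l2 (241 ± 57.5 against 2.22 ± 2.21 FPKM), Defb8 (916 ± 195 against 14.2 ± 3.93), Saa3 and Prg4 (26.9 ± 8.63 against 0.752 ± 0.192) rose, and Serpinb6e (-3.00, SE 0.25), Hamp2 (-2.56, SE 0.21) and Cyp2g1 (-1.85, SE 0.26) fell. The call of S100a9 (3.45, SE 0.95) ended without any 1 of the 8 libraries (adjusted p up to 0.15). Limma called 423 genes, 287 higher and 136 lower. Without the kidney set 403 were called, and 432 without the 4 low-Y treatment libraries of both days. Voom called 336, not counting Saa3, Prg4 and S100a9. Of 14 macrophage genes 6 rose (14 adjusted over the list alone, median 1.16, adjusted p = 0.469 with an estimated correlation) and of 6 erythrocyte genes 4 rose (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.469 with an estimated correlation). Of 10 keratinocyte stress genes 4 rose (5 adjusted over the list alone, median 0.92, adjusted p = 0.469 with an estimated correlation) and of 13 interferon genes 3 rose (9 adjusted over the list alone, adjusted p = 0.469 with an estimated correlation). Inner root sheath genes were at a median of -0.44 with 0 of 10 called by limma or voom (8 at an unadjusted p under 0.05, 7 lower adjusted over the list alone; adjusted p = 0.602 with an estimated correlation). The count was 155 without control replicate 1, 124 without control replicate 3, 135 without control replicate 4, 88 without treatment replicate 2, 83 without treatment replicate 3, 250 without treatment replicate 4, 2229 when only both groups set the spread and 4485 with array weights. S100a9 was also lost with no filter, with median-of-ratios scaling, without the kidney set and without the low-Y libraries.

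Treated and control skin at day 15 differed in 41 genes, 4 higher and 37 lower, and 2572 genes had an unadjusted p under 0.05. Voom called 10, with Serpinb6e, Skint3 and Wdr89 among them. Serpinb6e (4.97 ± 1.64 in control and 0.959 ± 0.904 FPKM in treated skin), Serpina3b (46.7 ± 8.77 and 19.2 ± 6.79), Skint3 (6.93 ± 0.401 and 2.69 ± 1.17), the progestin receptor gene Paqr7 and the peptide transporter gene Slc15a1 were lower, and Wdr89 (0.58, SE 0.10) was higher. Limma called 0 genes without treatment replicate 1 (1580 at an unadjusted p under 0.05), 0 when only both groups set the spread (1663) and 0 without the 4 low-Y libraries (1754, with replicate 3 alone as treated). None of the 9 named genes kept its call in every fit that left out 1 library. The count was 11 with a pseudocount of 0.1, 16 with no filter or a common total per library, 12 with quantile normalization and 20 at a mean FPKM of at least 5. Serpina3b and Slc15a1 were lost in the first 4 of these settings, Paqr7 in all 5, and Serpinb6e with a pseudocount of 0.1. The count was 1820 with array weights, 1 without control replicate 1, 5 without control replicate 2, 14 without control replicate 3, 2 without control replicate 4, 3 without treatment replicate 2 and 2665 without treatment replicate 3. Immediate early genes (0 of 12 called by limma or voom, 7 at an unadjusted p under 0.05, 6 higher adjusted over the list alone, median 0.68) and basal epidermis genes (0 of 10 called by both, 6 at an unadjusted p under 0.05, 5 lower adjusted over the list alone, median -0.24) passed as lists, each with an adjusted p = 0.92 with an estimated correlation, the latter not without treatment replicate 3 (adjusted p = 0.125). The immediate early list mean was 6.32 and 5.98 in the low-Y treatment replicates 2 and 4, and 4.93 and 4.41 in replicates 1 and 3, against 4.54 to 4.94 in control skin. Fos was at 43.7, 150 and 92.8 FPKM in the low-Y replicates 1, 2 and 4 and at 9.73 in replicate 3 (11.5 to 18.5 in control skin).

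Between day 10 and day 15 control skin changed in 627 genes (193 higher, 434 lower), model skin in 1104 (211 higher, 893 lower) and treated skin in 1257 (275 higher, 982 lower). Melanocyte genes fell with time in 5 of 11 in control (9 adjusted over the list alone, adjusted p = 0.504 with an estimated correlation) and 8 of 11 in model skin (10 adjusted over the list alone, adjusted p = 0.302 with an estimated correlation). Cell cycle genes fell in 9 of 27 in control (24 adjusted over the list alone, adjusted p = 0.504 with an estimated correlation) and 17 of 27 in model skin (26 adjusted over the list alone, adjusted p = 0.302 with an estimated correlation). Interferon genes rose in 3 of 13 in control (11 adjusted over the list alone, adjusted p = 0.504 with an estimated correlation) and 7 of 13 in model skin (13 adjusted over the list alone, adjusted p = 0.302 with an estimated correlation). In control skin Saa3 rose from 4.98 ± 0.682 to 377 ± 308 FPKM (not called by voom). In model skin Col11a1 fell from 14.9 ± 4.57 to 4.04 ± 2.81 FPKM (not called without model replicate 3 of day 15 at an adjusted p = 0.054, nor when only both groups set the spread). Kap fell to 0 in both, and without the kidney set 595 and 1097 genes were called. In treated skin the keratinocyte stress gene Krt6b fell from 19.4 ± 12 to 0.847 ± 0.744 FPKM, Ifi202b from 7.57 ± 4.4 to 0.632 ± 0.461 and S100a7l2 from 241 ± 57.5 to 57.5 ± 62.6. Krt72 rose from 227 ± 25.4 to 557 ± 101 and Alox12 from 2.32 ± 0.292 to 8.41 ± 3.45. Sebaceous genes fell in 7 of 12 (9 adjusted over the list alone, median -0.94, adjusted p = 0.566 with an estimated correlation) and basal epidermis genes in 7 of 10 (8 adjusted over the list alone, adjusted p = 0.566 with an estimated correlation) in treated skin. Immediate early genes rose in 6 of 12 (9 adjusted over the list alone, adjusted p = 0.566 with an estimated correlation), with list means of 6.32 in replicate 2 and 4.41 in replicate 3 of day 15. In treated skin 967 genes were called without the low-Y libraries (replicate 3 alone at day 15), Ifi202b not among them, and S100a7l2 was not called when only both groups set the spread. Each of these contrasts sets mice killed on 1 day against mice killed on another, so time and day of sampling cannot be told apart.

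Counts between days moved with single libraries. The control count was 199, 123 and 195 without day 10 replicates 1, 2 and 4 and 122, 102 and 99 without day 15 replicates 1, 2 and 4. The model count was 391, 480 and 267 without day 10 replicates 2, 3 and 4 and 146 without day 15 replicate 3. The treatment count was 724, 425 and 614 without day 10 replicates 1, 2 and 4, 487 without day 15 replicate 1 and 2531 without day 15 replicate 3. When only both groups set the spread the counts were 1938, 8 and 440 for control, model and treated skin. Median-of-ratios scaling gave 376 and 501 genes in control and model skin and turned the balance, with 225 and 271 higher against 151 and 230 lower. At a mean FPKM of at least 5 the counts were 330, 701 and 826, and with array weights 3683, 3347 and 2609. A common total per library gave 968 genes in control and 1982 in treated skin, and moved the median of all genes to -0.10, -0.11 and -0.13.

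The treatment-model difference itself changed between days in 13 genes (8 higher, 5 lower), and 1884 had an unadjusted p under 0.05. Of these 13, 7 belong to the kidney set, and without that set limma called 0 genes (1877 at an unadjusted p under 0.05), while voom on all genes called 13. The other 6 were Fdps, a cholesterol synthesis enzyme (0.59, SE 0.11), Grem1 (-1.87, SE 0.35), Sectm1a (-1.54, SE 0.29), Rin2 (-0.59, SE 0.10), Dnajb9 (-0.58, SE 0.11) and Mcfd2 (-0.54, SE 0.10). None of the 6 was called when only the groups compared set the spread, and Fdps was also lost with voom, a common total per library or quantile normalization. At a mean FPKM of at least 5 Fdps, Grem1 and Dnajb9 were lost. Rin2 lost its call in 4 fits that left out 1 library (adjusted p up to 0.063) and the others in 5 to 11. The count was 7 when only the groups compared set the spread, 7 without model replicate 2 or treatment replicates 2 or 4 of day 10, 41 without treatment replicate 1 of day 10, 94 without model replicate 1, 35 without treatment replicate 3 and 25 without treatment replicate 4 of day 15, and 408 without the low-Y libraries (replicate 3 alone for treatment at day 15). It was 56 with no filter, 3 at a mean FPKM of at least 5 and 596 with array weights.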

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

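The 3 tests of the kidney transcripts, the test of library scale and both tests of day 15 treatment replicate 3 were chosen only after the results were seen. The test of X-linked genes and the counts of splits were chosen before, and which labels a split exchanged was counted after. Chance finds about 1 in 20 sets of 4 libraries as having a member far from the other 3. Here 14 of 216 sets of list means and 12 of 225 sets of gene values had one.

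Among means of gene lists, as log2(FPKM + 1), 1 library lay far from the other 3 of its group in these cases. At day 10 they were the BMP pathway (model replicate 1 at 3.8, others 3.57 to 3.61), bulge stem cells (treatment replicate 2 at 3.85, others 3.92 to 3.93) and the androgen and follicle panel (control replicate 2 at 3.34, others 3.28 to 3.29). Mast cells (model replicate 1 at 2.94, others 3.71 to 3.86) and antigen-presenting cells (model replicate 1 at 5.24, others 5.46 to 5.49) belong there too. So do interferon response genes (control replicate 4 at 1.92, others 2.20 to 2.23) and xenobiotic and antioxidant response genes (control replicate 3 at 3.96, treatment replicate 1 at 4.11). At day 15 they were keratin-associated proteins (treatment replicate 4 at 7.26, others 7.03 to 7.06) and melanocytes (treatment replicate 3 at 3.65, others 3.37 to 3.41). Epidermal differentiation (model replicate 3 at 4.80, others 5.44 to 5.52) and dermal extracellular matrix (control replicate 2 at 7.11, others 7.24 to 7.25) follow. The last are mast cells (control replicate 1 at 3.63, others 2.88 to 2.98) and the BMP pathway (control replicate 1 at 3.62, others 3.76 to 3.78).

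Among named genes, on the same scale, the distant library at day 10 was model replicate 1 for Hamp2 (0.44, others 0), model replicate 3 for Car6 (4.21) and control replicate 2 for Sprr2h (2.93). It was control replicate 3 for Lef1 (4.69) and model replicate 2 for Poglut3 (4.10). Treatment replicate 1 was low for Krt16 (3.56, others 6.13 to 6.49) and Sprr1b (3.78, others 5.22 to 5.51). At day 15 it was control replicate 3 for Saa2 (0.56, others 1.85 to 1.98), control replicate 1 for C7 (5.18), model replicate 3 for Sprr2h (4.15) and control replicate 4 for Lce3c (3.01). Model replicate 1 of day 10 was the distant library in 4 sets, the most of any library.

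The treatment-model difference changed between days, by a test of that change, in 13 genes. As fitted differences on the log2(FPKM + 1) scale, the kidney genes Kap (4.11), S100g (1.61), Miox (1.24), Slc27a2 (1.20), Umod (1.19) and Slc34a1 (1.04) moved up. Their levels at day 15 are near or at 0 in every group. The others were Fdps (0.59), Grem1 (-1.87), Sectm1a (-1.54), Rin2 (-0.59), Dnajb9 (-0.58) and Mcfd2 (-0.54).

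List tests on the changes between days were added after seeing the data. For the model-control difference, lists past the threshold had these median changes: hair shaft keratins 0.42, endothelium 0.19, sebaceous gland -0.27, cholesterol synthesis -0.11, adipocytes -0.55, basal epidermis -0.11, epidermal differentiation -0.22, macrophages -0.53 and circadian clock -0.20. Each had an adjusted p = 0.964 with an estimated correlation. For the treatment-model difference the medians that moved up were inner root sheath 0.43, hair matrix regulators 0.48, Wnt targets 0.39, Hedgehog pathway 0.44, melanocytes 0.51 and cell cycle 0.37. Cholesterol synthesis (0.21), immediate early genes (0.53) and mitochondrial oxidative phosphorylation (0.18) also moved up. The medians that moved down were basal epidermis -0.35, keratinocyte stress -1.12, dermal extracellular matrix -0.47, macrophages -0.46, neutrophils -1, mast cells -0.35, interferon response -1.25 and xenobiotic response -0.20. These 17 lists had an adjusted p between 0.476 and 0.689 with an estimated correlation.

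Kidney transcripts were present in the 8 control and model libraries of day 10, with Kap at a mean of 19.1 FPKM, S100g at 2.33 and Umod and Miox at 1.55, and at or near 0 in the other 16. Induction by DHT in skin is argued against, since the median log2 difference between model and control over the 18 kidney genes was -0.17. RNA or reads from kidney in these libraries stays open, because 50% of a separate kidney list (13 of 26 genes, at 0.647 FPKM or less) had means in the 8 above each of the other 16, which lies between its bounds (at most 7.7% over 14 other pairs of groups). RNA or reads from several organs in these libraries stays open too: 23.8% of 21 genes of other organs were above (at most 9.5% in other pairs), over the bound of 20%, but all at 0.329 FPKM or less, too near 0 to decide. Neither can be told apart from an untested difference between mice, and any of these confounds comparisons of these 8 libraries with others.

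Y-linked transcripts were lower by a log2 difference of -0.61 in 4 treatment libraries (day 10 replicate 3, day 15 replicates 1, 2 and 4) than in the other 20. RNA from female mice in these libraries is argued against, because X-linked genes that escape inactivation differed by -0.16 (SD 0.15 over the other 20), not upward. A change of library scale is argued against by a median over all tested genes of -0.04. A difference between the mice themselves, or an effect of the extract on these genes, may remain and was not tested.

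Day 15 treatment replicate 3 lay near the control libraries. Over the 918 genes lowered at day 10 it was at position 0, and over the 885 raised genes at -0.79, beyond the controls of its day (-0.33 to 0.31). A weaker androgen response of every responsive gene in this mouse is argued against by the difference of 0.79 between both positions. A control library under a treatment label cannot be told apart from a strong response to the extract: the lowered genes sit at the control level, but Hamp2 was at 0.0618 FPKM (controls 0.913 to 3.45) and Serpinb6e at 0.821 (controls 3.63 to 7.34). It could be either, and it is also the 1 treatment library of day 15 with a usual Y-linked level (3.39) and with Fos at 9.73 FPKM against 43.7 to 150 in the other 3.

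Other splits of the same libraries were counted for each comparison, the real split included. Chance is excluded for model against control at day 10, where 1 of 35 splits called as many genes (1803, highest other split 1166), and at day 15 (1 of 35, 1408, highest other 2). It is also excluded for treatment against model at day 10 (1 of 35, 25, highest other 9) and day 15 (1 of 35, 2563, highest other 2158) and for treatment against control at day 10 (1 of 35, 423, highest other 1). For the change with time the real split ranked first in control (1 of 35, 627, highest other 1) and model skin (1 of 35, 1104, highest other 544). Other splits called as many genes for treatment against control at day 15 (4 of 35, 41, highest other 1990) and for the change with time in treated skin (2 of 35, 1257, highest other 2390). Chance cannot be excluded for these. Nor can it be for the change of the treatment-model difference (7 of 100, 13, highest other 1146). For the change of the model-control difference the count decides nothing: limma called 0 genes (352 at an unadjusted p under 0.05, 0 by voom), so 100 of 100 splits call as many by design (highest other 2891). The highest splits of both changes exchanged 3 labels at day 15 and 0 (model-control) or 1 (treatment-model) at day 10, which can turn a difference between groups into a change between days. The split with 1990 calls points to a structure of the samples other than their groups.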

How the results depend on the processing

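Voom, the fit without the low-Y libraries and the fit without kidney genes were tests chosen only after the results were seen; the other alternatives were planned. Where a value moved, the cause was not tested unless stated. Libraries left out leave fewer samples, and a stricter filter fewer genes. Depth limits genes at low FPKM, and no filter adds genes near 0. The lone day 15 treatment library in the fit without low-Y libraries is replicate 3, whose label is left open, and is assumed to vary like the other groups. No list past the threshold turned its median direction under another scaling.

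With an estimated correlation, 2 of 11 lists still passed for treatment against model at day 10. In the other comparisons 0 lists passed by limma's camera, against 15 and 22 for model against control at days 10 and 15, 14 for treatment against model at day 15, 19 and 11 for treatment against control, and 20, 21 and 13 for the changes with time in control, model and treated skin.

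Counts that moved by over 1.5 times were as follows. Treatment against control at day 15 (41 genes) gave 11 with a pseudocount of 0.1, 16 with no filter, 20 at a mean FPKM of at least 5, 16 with a common total per library, 12 with quantile normalization and 10 with voom. Treatment against model at day 10 (25 genes) gave 101 with no filter, 10 at a mean FPKM of at least 5, 15 with voom and 14 without the kidney genes. The change of the treatment-model difference (13 genes) gave 56 with no filter, 3 at a mean FPKM of at least 5, 408 without the low-Y libraries and 0 without the kidney genes (limma, 1877 at an unadjusted p under 0.05; voom on all genes 13). The changes with time in control, model and treated skin (627, 1104 and 1257) gave 330, 701 and 826 at a mean FPKM of at least 5. Median-of-ratios scaling gave 376 and 501 in control and model skin, and a common total per library 968 in control and 1982 in treated skin.

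With only the groups compared, limma called 724 genes for model against control at day 15 (1408), 2229 for treatment against control at day 10 (423), and 1938, 8 and 440 for the changes with time. It called 7 for the change of the treatment-model difference (13), and 0 for treatment against model (2563, now 2503 at an unadjusted p under 0.05, voom on all groups 2574) and treatment against control at day 15 (41, now 1663, voom on all groups 10). With array weights the counts were 4927 and 4592 for model against control, 1502 for treatment against model at day 10, 4485 and 1820 for treatment against control, 3683, 3347 and 2609 for the changes with time, and 66 and 596 for the changes of the model-control and treatment-model differences. Without the low-Y libraries treatment against model at day 15 gave 3845 genes, 1392 of them among the 2563, and treatment against control 0 (limma, 1754 at an unadjusted p under 0.05). Between treatment and model Tgfb1 turned there from 0.03 (not called) to -0.70, from replicate 3 alone.

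With the replicate number as a block, counts were 923 for model against control at day 15, 204 and 3 for treatment against control, and 298, 587 and 755 for the changes with time. The numbers do not pair the libraries: 8 of 24 same-numbered pairs had residual correlations over 0.1 (-0.63 to 0.51), and 7 of 24 libraries matched their own number best.

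The share of higher calls moved by over 10 points in these cases, as higher and lower. A common total gave 1071 and 604 for model against control at day 10 (885 and 918), 735 and 472 at day 15 (552 and 856), 686 and 1676 for treatment against model at day 15 (1348 and 1215) and 372 and 89 for treatment against control at day 10 (287 and 136). It gave 165 and 1817 for the change with time in treated skin (275 and 982) and 7 and 7 for the change of the treatment-model difference (8 and 5). Median-of-ratios scaling gave 300 and 85 for treatment against control at day 10, and 225 and 151, 271 and 230, and 570 and 668 for the changes with time in control (193 and 434), model (211 and 893) and treated skin. Quantile normalization gave 1739 and 933 for treatment against model at day 15, and 192 and 256, 271 and 511, and 369 and 496 for the changes with time.

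With separate model libraries (split 2 and 2) the correlation of both effects averaged -0.209 at day 10 (-0.366) and -0.447 at day 15 (-0.749). Leaving out 1 library gave r of -0.545 to -0.272 and -0.838 to -0.490. Gene counts then ran from 536 to 2405 and 363 to 2240 for model against control, 14 to 82 and 1221 to 2947 for treatment against model, and 83 to 497 and 0 to 2665 for treatment against control. They ran from 99 to 828, 146 to 1522 and 425 to 2531 for the changes with time in control, model and treated skin, and from 0 to 3 and 7 to 94 for the changes of the model-control and treatment-model differences. Both limits of 0 are limma's, with 1580 genes at an unadjusted p under 0.05 for treatment against control and 265 to 471 for the model-control difference. List counts ran from 12 to 16 and 13 to 22, 8 to 12 and 11 to 17, 15 to 21 and 9 to 14, and 16 to 19, 20 to 23 and 12 to 14 in the same order. Of the named called genes, 41 of 59 and 26 of 65 kept their call in every such fit for model against control, 9 of 17 and 48 of 72 for treatment against model, and 9 of 10 and 0 of 9 for treatment against control.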

Other observations

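Gene Ontology enrichment was chosen only after the values were seen. Called genes were set against 12509 annotated tested genes with a one-sided exact test adjusted over terms, which treats genes as independent, and genes are not independent replicates. In model skin at day 10 the higher genes held 49 of 225 genes of collagen-containing extracellular matrix (15.5 expected, adjusted p = 8.81e-10), 62 of 360 lysosome genes (24.8 expected) and 9 of 12 genes of the classical complement pathway (0.8 expected, adjusted p = 2.5e-06). The lower genes held 49 of 98 intermediate filament genes (6.7 expected, adjusted p = 7.37e-28). At day 15 the higher genes held 27 of 153 genes of defense response to virus (6.6 expected, adjusted p = 3.48e-07) and the lower genes 16 of 26 keratinization genes (1.7 expected, adjusted p = 3.03e-10).

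In treated against model skin at day 10 the 12 higher genes held 7 of 26 keratinization genes (exact test, adjusted p = 1.81e-13). At day 15 the higher genes held 85 of 240 translation genes (24.9 expected, adjusted p = 2.27e-22) and 24 of 56 proteasome genes (5.8 expected, adjusted p = 1.69e-07). The lower genes held 42 of 153 genes of defense response to virus (14.2 expected, adjusted p = 2.28e-07). When only both groups set the spread limma called 0 genes of that day (2503 at an unadjusted p under 0.05, voom 2574 on all groups), so these shares rest on the spread of all 6 groups.

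The smallest p-values for a change of the model-control difference between days were those of Rfx2 (-1.49, adjusted p = 0.063) and Klf16 (-0.72, adjusted p = 0.089), and neither was called.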
